A study of Homo sapiens with 24 samples.

How the data were processed

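RNA from 24 samples of A549 cells treated with conditioned medium of bone marrow mesenchymal stem cells was amplified with amino allyl chemistry, labelled with Cy5 and hybridised to one-colour arrays, per the labels' protocols. The deposited table holds the authors' intensity of each of 31741 probes on a linear scale, with between 51 and 101 values at or below 0 per array, as subtraction of a background gives. The scaling between arrays, the scanner settings and any filter are not given in the sources used here; array medians differed, so the values were not quantile normalized. Centring is absent and the direction of the values is that of brightness. All 24 columns of the table were matched to samples by their own labels, and 0 columns were left unused. Groups and replicate numbers come from the sample titles. Untreated samples were not analysed here.

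Intensities under 16 were set to 16 and log2 was taken. The floor was chosen after seeing that some values were below 0 and before any test was run. Apart from the additions marked below as made after seeing the data, the design was otherwise fixed before the data were examined. Of the probes, 24658 had exactly 1 gene symbol, 1002 had several and 6081 had none in the platform annotation, and the last 2 kinds were named nowhere. Symbols were brought up to date through a RefSeq table: 22404 were current, 2177 were replaced through a synonym and 77 had no match and kept their old form. Of the probes of a gene, the one with the highest mean over all arrays was tested, which gave 18255 genes, 5450 of them with more than 1 probe.

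One linear model with a mean for each of the 8 times was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend of the prior variance), and p-values were adjusted by Benjamini and Hochberg within each comparison, with 0.05 as threshold and all tests two-sided. The comparisons were an F test over the times, each time against 2 h, each neighbouring step, the late times (24, 48, 72 and 96 h) against the early (2, 4, 8 and 16 h), and the middle times (8, 16 and 24 h) against both ends (2, 4, 72 and 96 h). Gene lists (31, all with at least 5 tested genes, 3 of them markers of other cell types, 1 of alveolar and airway cells and 1 of housekeeping genes) were fixed before the data were examined. They were tested against other genes with camera at a preset correlation of 0.01 and with an estimated one. A list score per array is the mean, over the list, of log2 intensity minus the gene's mean over 24 arrays; its one-way F over times was tested with 100000 permutations of the arrays, and within 2 to 8 h and within 24 to 96 h by enumerating all 280 and 15400 groupings, which was added after seeing the data. Permutations ran in Python 3.11.15 with numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

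The largest rises and falls were taken from genes that passed the test in the comparison and had a mean above the median of tested genes (8.77 on the log2 scale), 10 each for late against early, 5 each for middle against both ends, 3 each against 2 h and 2 each per step. To these were added 28 genes fixed in advance, 27 of them tested, and up to 4 members with the largest change of each list described, which were not held to that level. Of the list members named, FOSB, CXCL8, CDKN2B, H2AC6, H3C10, COL4A1, ACTA2 and JUNB lay below it, as did CDH2, FN1, CD44, PROM1, TWIST1, SOCS3, VIM, SNAI2, ZEB1, ZEB2 and IL6 of the genes fixed in advance. For genes with 2 probes above the median level, the changes of both probes were correlated, with 1000 bootstrap draws over genes; this check was added after the step at 16 h was seen.

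Alternatives were quantile normalization, a common median, leaving out the dimmest 25% or 50% of genes, no intensity trend, all probes, the mean of a gene's probes, a replicate block, a fit of only the arrays compared, an offset of 50, the median over a list, an estimated correlation, and each array or replicate number left out in turn. The model was tested on simulated data for 96 h against 72 h over 18255 genes, with each gene's real mean and 1 spread per gene. Noise was normal and independent, and all changed genes lay above the median level. Of genes changed by 0.5 on the log2 scale, 58.2% were recovered. The share was 86.6% for a change of 1 and 100% for a change of 2, with 5 calls among 18055 unchanged genes. Recovery among dimmer genes was not tested, and far fewer genes were changed than were called in the real data.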

Results

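Gene expression was measured in A549 cells, an established line from a human lung adenocarcinoma, after treatment with medium conditioned by bone marrow mesenchymal stem cells. The series title places the work in the setting of STAT3 phosphorylation and the switch between epithelial and mesenchymal states. The 24 one-colour arrays fall into 8 times after the start of treatment, the early ones at 2, 4, 8 and 16 h and the late ones at 24, 48, 72 and 96 h, with 3 arrays at each. The series design also names untreated cells at the same times; these were not analysed here, so every comparison is between times of treated cells and does not separate the treatment from time in culture. Nothing in the labels says that the 3 arrays of a time came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Each array gave an intensity for 31741 probes, with a median between 185 and 272, and between 1.09% and 6.58% of probes lay under the floor of 16 used before taking log2. The number of arrays limits the precision of each value.

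Of 18255 genes tested, 16889 changed over the 8 times (limma F test, adjusted p under 0.05). With so many passing, this test singles out no gene list. Arrays of 1 time correlated with each other at r between 0.988 and 0.997 across genes, and arrays of different times at r between 0.919 and 0.994. The mean correlation was 0.984 between 2 and 8 h, 0.966 between 8 and 16 h, 0.977 between 16 and 24 h and 0.978 between 72 and 96 h. Among the late times it lay between 0.972 (24 with 96 h) and 0.992 (24 with 72 h). Between 2 and 8 h alone, 605 genes changed, and between 24 and 96 h alone 10365; both of these counts were added after seeing the data. The median SD between replicates was 0.209, 0.183 and 0.191 at 2, 4 and 8 h and between 0.107 and 0.176 at the later times (log2 scale), while the fit uses 1 spread per gene for all times. Scores of all 31 gene lists changed over the 8 times (permutation test, adjusted p under 0.05). Of these, 14 passed an exact permutation test within 2 to 8 h alone and 28 within 24 to 96 h alone.

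Genes with more than 1 probe gave a check on each comparison that does not depend on the test. For 1766 genes with 2 probes above the median level, the log2 changes of both probes correlated across genes at r = 0.40 for 4 h against 2 h, 0.44 for 8 h against 4 h, 0.64 for 48 h against 24 h, 0.47 for 72 h against 48 h and 0.80 for 96 h against 72 h. In the step from 8 to 16 h the correlation was -0.01 (95% bootstrap interval from -0.056 to 0.045) and in the step from 16 to 24 h it was 0.04 (from -0.013 to 0.083). Genes are not independent replicates in these correlations. Where both probes of a gene passed the test, they moved in opposite directions for 391 of 765 genes from 8 to 16 h and for 24 of 713 from 72 to 96 h. Steps within 2 to 8 h and within 24 to 96 h are therefore described first, and comparisons that cross 16 h are given with this value beside them.

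**Figure D1:**
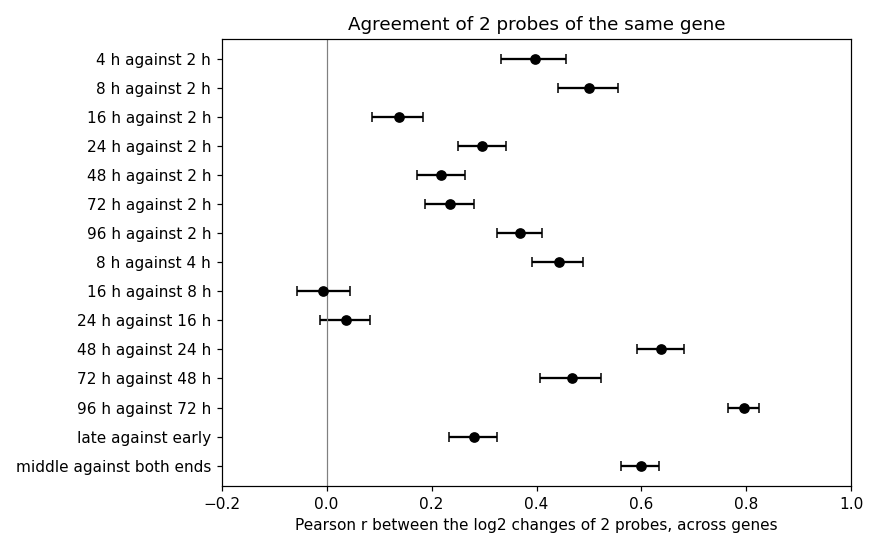
Pearson correlation, across 1766 genes, between the log2 changes of 2 probes of the same gene in each of the 15 comparisons; points are correlations and bars are 95% bootstrap intervals over genes. The correlation was -0.01 from 8 to 16 h and 0.04 from 16 to 24 h, against 0.80 from 72 to 96 h.

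Between 2 and 8 h, transcripts of early signalling and of sterol synthesis fell and those of mitosis and of ribosome assembly rose. The chemokine CCL20 changed by -3.83 ± 0.10 (SE; adjusted p = 5.57e-16) on the log2 scale, and INSIG1, a sterol-regulated inhibitor of cholesterol synthesis, by -3.30 ± 0.13 (SE; adjusted p = 1.67e-12); the second INSIG1 probe gave -2.96. ARL14, a small GTPase, changed by -2.86 ± 0.11 (SE; adjusted p = 7.31e-13). The largest rises were those of the potassium channel gene KCNJ8 (1.92 ± 0.15), the carboxypeptidase gene CPA4 (1.91 ± 0.16) and the cyclin gene CCNF (1.72 ± 0.10). Among immediate early genes, 24 of 38 fell and 1 rose (2 higher and 27 lower when adjusted over the list alone), including FOSB (-2.83, below the median level of all genes), ATF3 (-2.42) and JUND (-1.84). Of 37 NF-kB and inflammatory genes, 14 fell and 2 rose (2 higher and 15 lower when adjusted over the list alone), with CXCL8, also below that level, at -2.35 and the inhibitor NFKBIA at -1.30. Genes of the cholesterol synthesis list fell in 15 of 28 cases and rose in 1 (2 higher and 16 lower when adjusted over the list alone). They included HMGCS1 (-2.34), IDI1 (-1.53) and SQLE (-1.39). This list also holds genes with other roles, among them the regulators INSIG1 and SREBF1 and the fatty acid desaturase gene SCD.

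G2/M and mitosis genes rose in 28 of 44 cases over the same interval, with 1 lower (32 higher and 1 lower when adjusted over the list alone). NEK2 changed by 1.43, the checkpoint kinase BUB1 by 1.36 and the mitotic kinase PLK1 by 1.34. Ribosome biogenesis genes rose in 26 of 38 cases with none lower (27 higher and 0 lower when adjusted over the list alone), led by UTP20 (1.02), LYAR (0.96) and RRS1 (0.96). Of 21 heat shock genes 9 rose (10 higher and 0 lower when adjusted over the list alone), HSPA1B by 1.42. Among TGF-beta response and p53 target genes, 11 of 32 and 11 of 31 fell and 2 and 4 rose (11 and 15 lower when adjusted over the list alone). CDKN1A, a cyclin-dependent kinase inhibitor on both lists, changed by -2.48 and CDKN2B, below the median level, by -2.44. Of 38 ATF4 and amino acid response genes 16 fell and none rose (0 higher and 18 lower when adjusted over the list alone). These 9 lists, sterol and early signalling genes included, passed camera with the preset correlation (adjusted p = 6.05e-14 for immediate early genes) and with an estimated one, where the largest adjusted p was 0.037, for TGF-beta response genes. Some lists share members, so they are not independent, here or in later steps. ATF3 is on the immediate early and ATF4 lists, and IER3 on the immediate early and NF-kB lists. BTG2 is on the immediate early and p53 lists, and GDF15 on the p53 and ATF4 lists. Over all genes, 4164 passed the test at 8 h against 2 h, 2158 higher and 2006 lower, 1002 at 4 h against 2 h (598 higher) and 717 at 8 h against 4 h (314 higher). A fit of only the arrays compared (6 each) called 697, 10 and 1 genes, and without 2 h replicate 1 the counts against 2 h were 2403 and 455. With each array shifted to a common median, 44.5% of the calls at 4 h against 2 h were higher, against 59.7%. The share was 46.3% against 51.8% at 8 h against 2 h and 51.3% against 43.8% at 8 h against 4 h, so these majorities turned with scaling.

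In the earlier of these steps, 4 h against 2 h, 19 of 38 immediate early genes fell and 2 rose (2 higher and 25 lower when adjusted over the list alone; camera adjusted p = 1.90e-19). FOSB changed by -2.42, ATF3 by -1.70 and NR4A1 by -1.33. The epithelial transcription factor gene OVOL1 changed by -1.75 ± 0.18 (SE; adjusted p = 6.41e-06), with -1.86 on its second probe. The keratin-associated protein gene KRTAP3-1 changed by 1.63 ± 0.15, NHS by 1.37 ± 0.30 and the mitochondrial ribosomal protein gene MRPL21 by 1.36 ± 0.38. In the fit of only these 6 arrays OVOL1, KRTAP3-1, NHS and MRPL21 lost their calls (adjusted p = 0.0593, 0.0566, 0.363 and 0.427). Without 2 h replicate 1, NHS changed by 0.96 (adjusted p = 0.0742) and MRPL21 by 1.07 (adjusted p = 0.234), and without 4 h replicate 1 by 1.14 (adjusted p = 0.0575) and 0.80 (adjusted p = 0.215). From 4 to 8 h, CCL20 changed by -2.11 ± 0.10 (SE; adjusted p = 4.83e-11), RELB by -1.31 and HMGCS1 by -1.69, while the cohesin protector gene SGO2 changed by 1.18 ± 0.23 and the mitosis genes NEK2 and BUB1 by 1.07 and 0.99. SAMD12 changed by 1.11 ± 0.14 on its brightest probe and 0.09 on the second, and LBH fell to 0.25 of its 4 h level, a call lost without 8 h replicate 3 (adjusted p = 0.0944). The calls of SGO2, SAMD12 and LBH were also lost in the fit of only these arrays (adjusted p = 0.216, 0.175 and 0.187). Without 4 h replicate 1 or 3, 448 and 401 genes passed from 4 to 8 h, and without 4 h replicate 1 661 passed from 2 to 4 h.

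**Figure D2:**
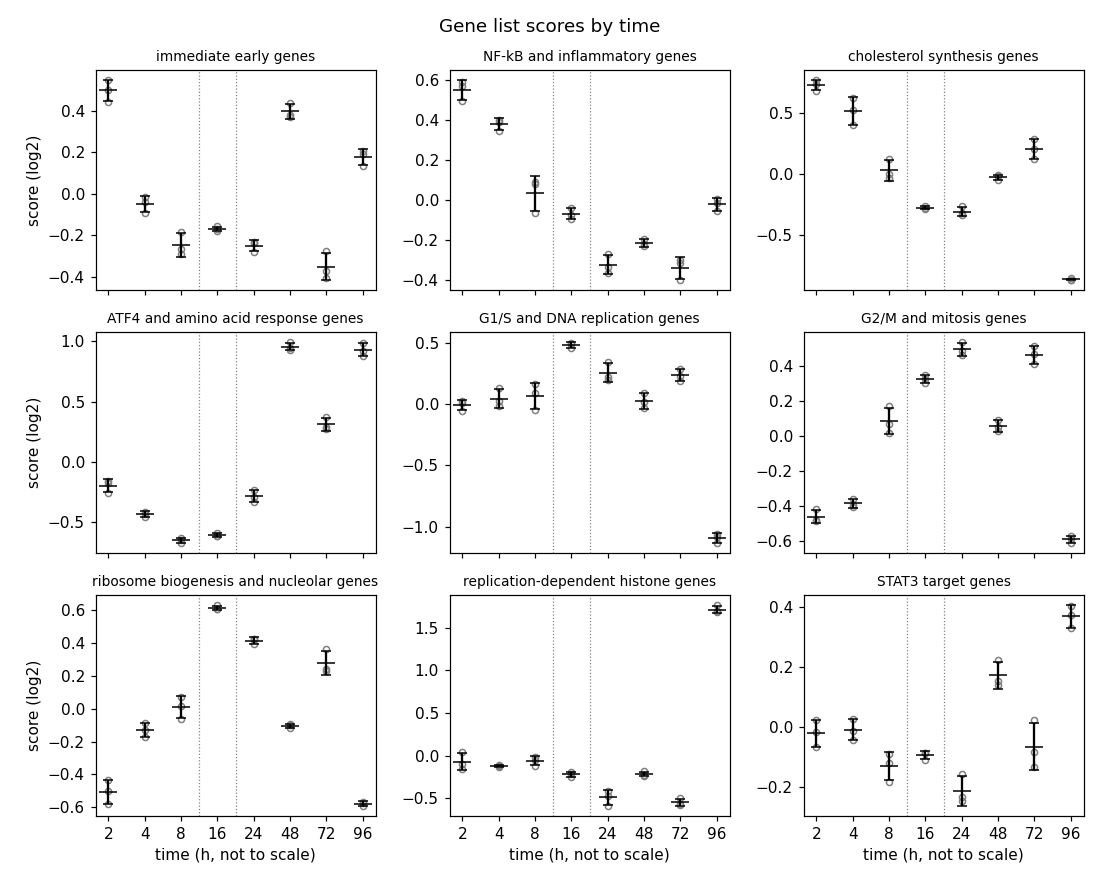
Scores of 9 gene lists at 8 times; each score is the mean, over a list, of log2 intensity minus the gene's mean over 24 arrays. Open circles are arrays, dashes and bars are the mean and SD of 3 arrays, and dotted lines mark the 2 steps in which probes of the same gene disagreed. The ATF4 and amino acid response score was -0.29 ± 0.05 at 24 h, 0.96 ± 0.03 at 48 h, 0.31 ± 0.05 at 72 h and 0.93 ± 0.05 at 96 h (SD, n = 3).

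From 24 to 48 h, genes of the amino acid response rose and those of growth and division fell. NUPR1, a stress-induced chromatin protein gene, changed by 4.45 ± 0.16 (SE; adjusted p = 4.09e-13) and DDIT4, an inhibitor of mTORC1 signalling, by 3.33 ± 0.09 (SE; adjusted p = 1.77e-15). Of 38 ATF4 and amino acid response genes, 33 rose and none fell (36 higher and 0 lower when adjusted over the list alone), among them the serine synthesis gene PHGDH (2.36) and the glutathione-degrading enzyme gene CHAC1 (2.30). Immediate early genes rose in 23 of 38 cases and fell in 1 (28 higher and 1 lower when adjusted over the list alone), with FOS at 2.61, IER2 at 1.67 and EGR1 at 1.67. Ribosome biogenesis genes fell in 26 of 38 cases and G2/M genes in 26 of 44, with none higher in either list (27 and 28 lower when adjusted over the list alone). LYAR changed by -1.20, POLR1A, the largest subunit of RNA polymerase I, by -1.04 and the proliferation marker MKI67 by -1.32. Heat shock genes fell in 12 of 21 cases and rose in 2, and oxidative phosphorylation genes fell in 12 of 41 and rose in 2. The keratin-associated KRTAP3-1 changed by -2.69 ± 0.15 and the cytokine gene IL32 by -2.19 ± 0.08, with -1.95 on its second probe.

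These 6 lists (ATF4, immediate early, ribosome biogenesis, G2/M, heat shock and oxidative phosphorylation genes) passed camera with the preset and the estimated correlation (adjusted p = 1.26e-06 for ATF4 genes and 7.88e-04 for immediate early genes with the estimate). Interferon-stimulated genes rose in 18 of 38 cases, ISG20 by 2.03, but their call (adjusted p = 0.00367) was lost with an estimated correlation (adjusted p = 0.182). G1/S genes fell in 13 of 41 cases and rose in 1, a call also lost with an estimated correlation (adjusted p = 0.0582). In all, 5474 genes passed at 48 h against 24 h, 3846 higher and 1628 lower. The median of all genes shifted by 0.11 in this step, and the split depended on scaling: 70.3% of calls were higher in the values as deposited, 51.8% after quantile normalization and 30.6% with a common median. The medians of the lists named for this step had the same sign under these 3 scalings.

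Between 48 and 72 h the ATF4, immediate early, G2/M and ribosome biogenesis lists moved in the other direction. Of the ATF4 list, 23 of 38 genes fell and none rose (0 higher and 25 lower when adjusted over the list alone). NUPR1 changed by -1.73, DDIT4 by -1.72 and the secreted stress factor gene GDF15 by -1.63. Immediate early genes fell in 26 of 38 cases with none higher (0 higher and 27 lower when adjusted over the list alone); FOS changed by -2.85 ± 0.18 (SE; adjusted p = 6.56e-09) and EGR1 by -1.90. The lysosomal membrane gene LAMP3 changed by -1.97 ± 0.12. These lists kept their camera calls with an estimated correlation (the largest adjusted p was 2.29e-04, for ribosome biogenesis). G2/M genes rose in 17 of 44 cases and ribosome biogenesis genes in 17 of 38, with none lower; MKI67 changed by 1.01 and UTP15 by 0.97. Among STAT3 targets 8 of 34 fell and 1 rose (camera adjusted p = 0.00734, or 0.0372 with an estimated correlation), including LCN2 (-0.86) and CEBPB (-0.71). TUBA4A, an alpha tubulin gene, changed by 1.42 ± 0.16 and TMEM186 by 1.48 ± 0.34. Of all genes 2723 passed, 1204 higher and 1519 lower; 54.3% of calls were higher with a common median, against 44.2%, and without 48 h replicate 1 the count was 1792. Both steps use the 48 h arrays, so their changes are not independent of each other. Over 24 to 96 h alone, the time test of the score gave an exact permutation p of 2.60e-04 for the ATF4 list and 1.30e-04 for immediate early genes (n = 3 per time).

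The step from 72 to 96 h had more calls than any other step within either block of times. Replication-dependent histone genes rose in 11 of 15 cases with none lower (11 higher and 0 lower when adjusted over the list alone): the linker histone gene H1-2 changed by 4.19 ± 0.11 (SE; adjusted p = 1.09e-15), the core histone gene H2BC5 by 3.71 ± 0.11 (SE; adjusted p = 5.94e-15) and, below the median level, H2AC6 by 4.84 and H3C10 by 4.30. The second H2BC5 probe gave 3.76. H4C3, whose brightest probe did not pass (-0.06), fell on its second probe (-0.63, adjusted p = 0.025); histone genes are near-identical copies, so single members are uncertain. G1/S and DNA replication genes fell in 37 of 41 cases (1 higher and 38 lower when adjusted over the list alone), including the replication factor genes CDC45 (-2.67) and MCM2 (-2.36), and G2/M genes fell in 39 of 44 (0 higher and 42 lower when adjusted over the list alone), including AURKB (-1.77) and HMMR (-2.17). CDCA7, a cell cycle gene, changed by -3.24 ± 0.23 (SE; adjusted p = 7.00e-10) and the transcription factor gene MYB by -2.92 ± 0.16 (SE; adjusted p = 2.41e-11). Genes of the cholesterol synthesis list fell in 26 of 28 cases with none higher (0 higher and 26 lower when adjusted over the list alone). ACAT2 changed by -2.64 and the fatty acid desaturase gene SCD, also on this list, by -2.13. Oxidative phosphorylation genes fell in 31 of 41 (1 higher and 32 lower when adjusted over the list alone) and ribosome biogenesis genes in 29 of 38 (1 higher and 30 lower when adjusted over the list alone), with NDUFA9 at -1.45 and BOP1 at -2.18.

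ATF4 genes rose again from 72 to 96 h, 23 of 38 higher and 5 lower (25 higher and 5 lower when adjusted over the list alone), with NUPR1 at 3.14 and DDIT4 at 2.74. TGF-beta response genes rose in 19 of 32 cases and fell in 3 (19 higher and 3 lower when adjusted over the list alone), among them ID3 (2.30), SKIL (1.96) and KLF10 (1.94), and immediate early genes in 19 of 38, FOSB by 1.56. STAT3 target genes rose in 14 of 34 cases and fell in 4 (19 higher and 4 lower when adjusted over the list alone), led by lipocalin LCN2 (1.93 ± 0.16 (SE; adjusted p = 5.53e-09)), FOS (1.88) and CEBPB (1.53). FOS is on the immediate early list as well. Heat shock genes fell in 13 of 21 cases and rose in 2, with FKBP4 at -2.05 and HSPA8 at -1.82. HSPA1A, which has a near-identical copy and is uncertain, changed by 1.92. The camera calls of the 11 lists named for this step, from histones to heat shock genes, held with an estimated correlation, the largest adjusted p being 0.0379, for STAT3 targets and TGF-beta response genes alike. Of all genes 6901 passed, 3702 higher and 3199 lower, with 906 and 895 changed at least 2-fold. The majority turned with a common median, where 2990 were higher and 3823 lower (718 and 1146 at 2-fold). After quantile normalization 51.9% were higher, against 53.6% as deposited.

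The middle times (8, 16 and 24 h) were compared with both ends (2, 4, 72 and 96 h) by their means. CPA4 (1.89 ± 0.08 (SE; adjusted p = 1.78e-12)), the tetraspan gene MALL (1.65 ± 0.09), the co-chaperone gene FKBP4 (1.62 ± 0.09), IL32 (1.56 ± 0.05) and the matrix gene TNC (1.45 ± 0.11) had higher means at the middle times, and the 4 of these with a second probe moved the same way on it. NUPR1 (-3.02 ± 0.09 (SE; adjusted p = 2.51e-15)), DDIT4 (-2.25 ± 0.05), CCL20 (-1.96 ± 0.05), the epithelial transcription factor gene ELF3 (-1.74 ± 0.05) and TSC22D3 (-1.71 ± 0.07) had lower means there. A difference of means does not make each middle time the highest or lowest: CCL20 stood at 10.21 ± 0.13 at 8 h but 7.47 ± 0.14 at 72 h, and FKBP4 at 12.29 ± 0.33 and 12.69 ± 0.20. G2/M genes were higher in 41 of 44 cases, ribosome biogenesis genes in 35 of 38, G1/S genes in 33 of 41 and heat shock genes in 17 of 21; ATF4 genes were lower in 30 of 38 and immediate early genes in 23 of 38. Scores at 72 h lay above those at 8 h for G2/M (0.46 ± 0.05 against 0.09 ± 0.08), ribosome biogenesis (0.28 ± 0.07 against 0.01 ± 0.07), G1/S (0.23 ± 0.05 against 0.07 ± 0.11) and heat shock genes (0.25 ± 0.09 against -0.06 ± 0.06; SD, n = 3 each), and the lowest late scores were those at 96 h. These differences between 72 and 8 h were not tested. Of all genes 8019 passed, 3430 higher and 4589 lower, and probes of the same gene correlated at 0.60. Without the 16 h arrays, a setting added after seeing the data that compares times only within 2 to 8 h and within 24 to 96 h, 5849 genes passed, with 39 of 44 G2/M, 29 of 38 ribosome biogenesis, 29 of 41 G1/S and 13 of 21 heat shock genes higher and 30 of 38 ATF4 genes lower. All 5 lists kept their camera calls there with an estimated correlation, the largest adjusted p being 0.0011, for G1/S genes.

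The steps into and out of 16 h held many large changes of single probes. From 8 to 16 h the GTPase gene RAC1 changed by 4.14 ± 0.35 (SE; adjusted p = 8.31e-09) and TBP, the TATA-binding protein, by 4.01 ± 0.26 (SE; adjusted p = 2.17e-10), and UBAC2 by -2.35 ± 0.10 on its brightest probe but 0.27 on the second. CSF3 changed by -4.44 ± 1.66 (SE, adjusted p = 0.0301). The size of this change rests on 16 h replicate 1: without that array it was -0.78, and the call was kept. The CSF3 call was lost without 8 h replicate 1, 2 or 3 (adjusted p = 0.0685, 0.0576 and 0.0556) and in the fit of only these arrays (adjusted p = 0.254). From 16 to 24 h, the xenobiotic receptor gene AHR changed by 2.27 ± 0.37 and the zinc transporter gene SLC39A14 by 2.25 ± 0.11, with 0.15 and 0.21 on their second probes; the receptor genes GRM4 and OR1B1 changed by -2.54 ± 0.26 and -2.39 ± 0.12. ATF4 genes rose in 18 of 38 cases from 16 to 24 h and fell in 4 (camera adjusted p = 0.00813 with an estimated correlation). Ribosome biogenesis genes rose in 24 of 38 from 8 to 16 h and fell in 6, a call lost with an estimated correlation (adjusted p = 0.0767). In the test 9749 genes passed from 8 to 16 h and 9309 from 16 to 24 h. The share of higher calls was 48.1% and 28.6% in the values as deposited, and 34.2% and 71.2% with a common median. The correlation of -0.01 and 0.04 between probes of the same gene means that single genes with 1 probe are not settled by these steps.

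Against 2 h, CCL20 was lower at each of the 7 later times, with a log2 change of -5.71 at 16 h, -6.57 at 72 h and -4.50 at 96 h. CDKN1A changed by -3.59 ± 0.15 (SE; adjusted p = 3.19e-13) at 24 h, with -3.63 on its second probe, and INSIG1 by -3.88 ± 0.13 (SE; adjusted p = 1.19e-14) at 96 h, with -3.56. Among the other named falls, the chloride channel gene CLIC3 changed by -3.73 at 16 h, -3.84 at 24 h and -3.91 at 72 h. CSF3 changed by -4.62 at 16 h, a size that again rests on 16 h replicate 1. ARL14 and the endothelin gene EDN1 changed by -3.95 and -3.11 at 48 h, and JUN by -4.00 at 72 h. PHLDA2 changed by -5.34 ± 2.25 (SE; adjusted p = 0.038) at 96 h, a call lost without 96 h replicate 3 (-1.88, adjusted p = 0.366) and, at a similar size, without any single 2 h array. In the fit of only the arrays compared CSF3 and PHLDA2 lost their calls (adjusted p = 0.182 and 0.0973), and without 2 h replicate 1 CSF3 also did (adjusted p = 0.0511). Rises were led by RAC1, TBP and the helicase gene DDX39A at 16 h (4.39, 4.33 and 4.28), with TBP still at 4.24 at 72 h, the retinol saturase gene RETSAT at 24 h (3.69) and LRP11 at 48 h (4.34). At 96 h the largest were the RNA-binding protein gene YTHDC1 (5.12, with 0.27 on its second probe), BAMBI (4.77) and DDIT4 (4.53). Between 11971 and 13773 genes passed at 16 to 96 h, all against the same 2 h arrays, and probes of the same gene correlated between 0.14 and 0.37. The median change of all genes from 2 to 24 h was -0.34, and that of the dimmest 25% was -0.57. Of the calls at 16 h and at 24 h 44.5% and 34.4% were higher, or 33.9% and 48.4% with a common median.

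Comparing the late times (24 to 96 h) with the early ones (2 to 16 h), genes of the amino acid response had higher means. Not each late time lay above each early one: the ATF4 score was -0.29 ± 0.05 at 24 h, below -0.20 ± 0.05 at 2 h, and the highest scores were those at 48, 72 and 96 h. Of the ATF4 list 32 of 38 genes were higher and 4 lower (32 higher and 4 lower when adjusted over the list alone), with DDIT4 at 3.28 ± 0.04 (SE; adjusted p = 3.38e-21), CHAC1 at 2.92 ± 0.09 and NUPR1 at 2.67 ± 0.08; this was the 1 list of 31 whose camera call held with an estimated correlation (adjusted p = 2.16e-04). Unfolded protein response genes were higher in 20 of 27 cases, SEL1L by 1.60, with an adjusted p of 0.00223, or 0.0781 with an estimated correlation. The other large rises were those of YTHDC1 (2.89), RETSAT (2.87), PNISR (2.80), LRP11 (2.79), ULBP1 (2.73), USP43 (2.73) and PDP1 (2.68). On second probes YTHDC1 gave 0.18, ULBP1 0.35 and PDP1 1.44. Falls were led by KRTAP3-1 (-2.89 ± 0.07), CCL20 (-2.80 ± 0.05) and the mucin gene MUC5AC (-1.88 ± 0.06, with -1.89 on its second probe). KATNAL2 (-1.87) and CDH8 (-1.71) gave 0.25 and -0.43 on their second probes, and MALL (-1.74) gave -1.23. JUN (-1.81), LOC100129697 (-1.74), MSH5 (-1.74) and the lipase inhibitor gene ANGPTL4 (-1.72) had 1 probe each. Of all genes 14781 passed, 5652 higher and 9129 lower, around a median shift of -0.19. The excess of lower calls depended on scaling: 38.2% were higher as deposited and 47.3% with a common median. Of the changes of at least 2-fold, 1324 were higher and 1430 lower, but 1749 and 845 with a common median. In this comparison probes of the same gene correlated at 0.28. Of 1133 genes called on both probes, 402 moved in opposite directions.

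Markers of other cell types, and those of alveolar and airway cells, were mostly lower in this comparison. Mesenchymal stromal markers were lower in 16 of 24 cases, blood and immune markers in 19 of 19, endothelial markers in 12 of 14 and alveolar and airway secretory markers in 14 of 18, with medians of -0.40, -0.77, -0.55 and -0.48. The first 3 of these passed camera (adjusted p = 0.0448, 0.00223 and 0.0463) and none did with an estimated correlation (adjusted p = 0.37, 0.253 and 0.259). Of their genes, 5 of 24, 6 of 19, 3 of 14 and 3 of 18 lay above the median level of all genes.

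Scores of epithelial genes rose against those of mesenchymal genes between 24 and 96 h. The mesenchymal minus epithelial score was 0.32 ± 0.10 at 2 h, 0.26 ± 0.10 at 8 h, 0.00 ± 0.05 at 24 h, -0.20 ± 0.08 at 48 h, -0.33 ± 0.07 at 72 h and -0.57 ± 0.02 at 96 h (SD, n = 3, log2 scale). It changed over the 8 times (permutation p = 1e-05, the smallest that 100000 permutations can give) and over 24 to 96 h alone (exact permutation p = 6.49e-05, the smallest possible), but not over 2 to 8 h (exact permutation p = 0.757). Each single step from 16 h onward had an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 allow, and an adjusted p of 0.175 over the 7 steps. The epithelial score went from -0.16 ± 0.06 at 24 h to 0.37 ± 0.01 at 96 h and the mesenchymal score from -0.16 ± 0.05 to -0.20 ± 0.03; within 24 to 96 h the adjusted exact permutation p was 0.00108 for the epithelial and 0.0503 for the mesenchymal score, which passed without 24 h replicate 2, 72 h replicate 1 or 96 h replicate 3 (adjusted exact permutation p = 0.0142, 0.0313 and 0.0418). Within 2 to 8 h it was 0.0101 for the mesenchymal score, which went from 0.25 ± 0.04 to 0.09 ± 0.03. The score of mesenchymal stromal cell markers fell in the same interval, from 0.50 ± 0.16 to 0.25 ± 0.05 (adjusted exact permutation p = 0.0395). Endothelial (0.48 to 0.26), blood and immune (0.48 to 0.30) and alveolar and airway markers (0.52 to 0.26) fell as well, without passing. From 24 to 96 h the scores of all these markers rose, as the epithelial score did: stromal from -0.32 to -0.18, endothelial -0.44 to -0.24, blood and immune -0.60 to -0.29, and alveolar and airway -0.40 to -0.17. As lists, neither the epithelial nor the mesenchymal one passed camera from 72 to 96 h. Epithelial genes were higher in 13 of 34 cases and lower in 7 (adjusted p = 0.252). Mesenchymal genes were higher in 10 and lower in 7 of 39 cases (adjusted p = 0.734). Late against early, probes of the same gene correlated at 0.28. Of the epithelial genes, 17 were higher and 7 lower in this comparison (camera adjusted p = 0.0434, or 0.373 with an estimated correlation). In that comparison 27 mesenchymal genes were lower and 5 higher (adjusted p = 0.0682). Their median of -0.401 lay within the central 95% of 10000 random lists matched on level (-0.407 to 0.090), and that of the epithelial list, 0.142, just above its range (-0.305 to 0.141). Of the mesenchymal genes 18 of 39 lay above the median level of all genes, and of the epithelial 30 of 34. From 72 to 96 h, ELF3 changed by 1.96 ± 0.09 (SE; adjusted p = 1.16e-12), the keratin gene KRT7 by 1.81, the tight junction gene CLDN4 by 1.49 and the protease gene PRSS8 by 1.37. Of mesenchymal genes in that step, COL4A1 changed by -1.55 and ACTA2 by -1.12, both just below the median level, but the integrin gene ITGA5 by 1.48.

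**Figure D3:**
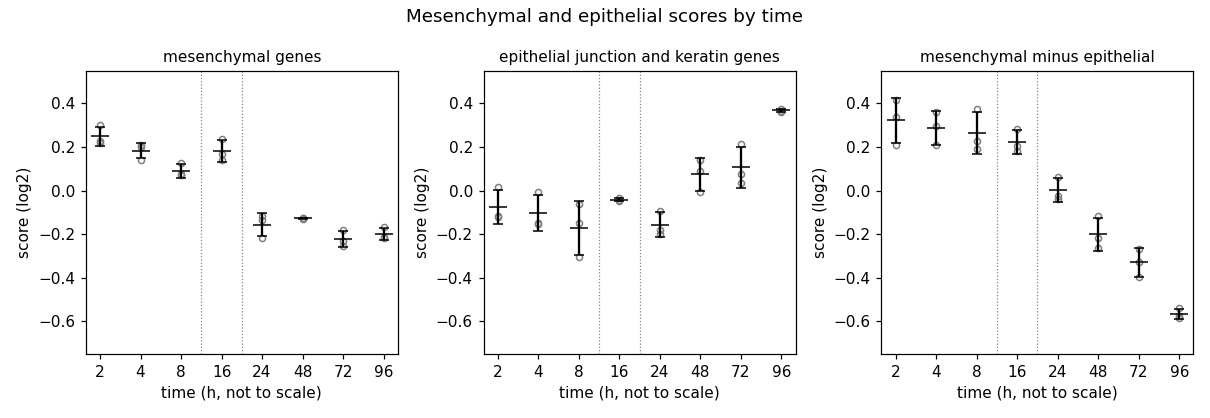
Mesenchymal score, epithelial score and their difference (log2) at 8 times; open circles are arrays, dashes and bars are the mean and SD of 3 arrays, and dotted lines mark the 2 steps in which probes of the same gene disagreed. The difference was 0.00 ± 0.05 at 24 h and -0.57 ± 0.02 at 96 h.

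Among genes fixed in advance for this question, CDH1, which encodes E-cadherin, had a log2 intensity of 14.45 ± 0.33 at 24 h and 15.58 ± 0.15 at 96 h and changed by 0.83 ± 0.17 (SE; adjusted p = 3.93e-04) from 72 to 96 h. Late against early its change was 0.12 (adjusted p = 0.176), which depended on scaling: it was 0.29 (adjusted p = 0.0028) after quantile normalization and 0.25 (adjusted p = 0.00882) with a common median. Under the other alternatives its adjusted p lay between 0.0899 and 0.551. Probes of the same gene correlated at 0.28 in this late against early comparison. From 72 to 96 h N-cadherin CDH2 changed by 0.55 ± 0.14 (SE; adjusted p = 0.00254), FN1 by 0.45 ± 0.11 (SE; adjusted p = 0.00269) and SNAI1 by -0.73 ± 0.12 (SE; adjusted p = 7.67e-05). CD44, a surface glycoprotein gene, changed by -1.63 ± 0.12 (SE; adjusted p = 1.20e-09) on its brightest probe and -0.05 on the second. MKI67 changed by -1.59 ± 0.11 (SE; adjusted p = 2.78e-10), PROM1 by -1.02 ± 0.09 (SE; adjusted p = 3.04e-08) and MYC by -0.70 ± 0.19 (SE; adjusted p = 0.00619). TWIST1 stood at 8.76 ± 0.06 at 2 h and 7.18 ± 0.06 at 96 h, and its change from 16 to 24 h was -1.86, in a step where the correlation between probes of the same gene was 0.04. EPCAM stood at 16.73 ± 0.21 and 16.56 ± 0.06. The VIM, SNAI2, ZEB1, ZEB2 and IL6 probes stayed below the median level of all genes (8.77) at all times, VIM between 5.80 and 6.35. Levels of different probes cannot be compared, so this does not show that these genes were weakly expressed.

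STAT3 itself went from 14.82 ± 0.15 at 2 h to 13.40 ± 0.11 at 96 h (log2 intensity, SD, n = 3). Its late against early change was -0.82 ± 0.06 (SE, adjusted p = 4.49e-10), with -0.51 on its second probe. Across genes, probes of the same gene correlated at 0.28 in this comparison and at 0.37 for 96 h against 2 h. From 8 to 16 h STAT3 changed by -0.67 (adjusted p = 2.19e-04), in a step where probes of the same gene disagreed. The 8 h against 2 h change was -0.36 (adjusted p = 0.0502) and lay near the threshold: its adjusted p was 0.0337 with a replicate block and ranged from 0.0288 to 0.201 over 15 alternatives, of which 5 passed. From 72 to 96 h it was -0.19 (adjusted p = 0.284). The cytokine gene LIF, an activator of STAT3 signalling, went from 13.28 ± 0.20 to 10.11 ± 0.08 and changed by -1.89 ± 0.11 (SE; adjusted p = 5.92e-10) already at 8 h. JUNB, a STAT3 target below the median level of all genes, changed by 1.37 ± 0.14 (SE; adjusted p = 3.99e-07) from 24 to 48 h and 0.92 ± 0.14 (SE; adjusted p = 1.78e-05) from 72 to 96 h. SOCS3 changed by 0.29 in the last step (adjusted p = 0.609). The STAT3 target score was -0.21 ± 0.05 at 24 h, 0.17 ± 0.05 at 48 h, -0.07 ± 0.08 at 72 h and 0.37 ± 0.04 at 96 h, and changed over 24 to 96 h (exact permutation p = 6.49e-05, n = 3 per time) but not over 2 to 8 h after adjustment (adjusted exact permutation p = 0.0615). FOS is also on the immediate early list. The immediate early score moved in the same directions, with -0.25 ± 0.03 at 24 h, 0.40 ± 0.04 at 48 h, -0.35 ± 0.07 at 72 h and 0.18 ± 0.04 at 96 h (SD, n = 3). The STAT3 target score is therefore not independent of the immediate early genes. Phosphorylation is not measured by these arrays. The scores of gp130 cytokines and receptors did not pass within 2 to 8 h (adjusted exact permutation p = 0.0615) or within 24 to 96 h (adjusted exact permutation p = 0.519). The latter rests on 1 array: 48 h replicate 2 had a score of -0.73, against 0.05 and 0.12 in the other 48 h arrays, and without it the gp130 score passed (adjusted exact permutation p = 0.00879, a test added after seeing the data).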

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

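The fits without 16 h, within 2 to 8 h and within 24 to 96 h, and the late list scores without single arrays, were chosen only after the result was seen, and the other alternatives before the data were examined. Leaving out the dimmest 50% of genes lowered the counts of called genes because fewer genes were tested: 8828 for the time test, 6479 for 16 h against 2 h, 6746 for 24 h against 2 h, 6567 for 48 h against 2 h, 6930 for 72 h against 2 h, 7078 for 96 h against 2 h, 5593 for 16 h against 8 h, 4600 for 24 h against 16 h, 7426 for late against early, 5109 for middle against both ends. In this setting 5 lists passed late against early instead of 9, and the cause was not tested. Testing all probes raised them because more were tested: 28799 for the time test, 6453 for 8 h against 2 h, 20565 for 16 h against 2 h, 22980 for 24 h against 2 h, 22540 for 48 h against 2 h, 23578 for 72 h against 2 h, 23236 for 96 h against 2 h, 16691 for 16 h against 8 h, 16073 for 24 h against 16 h, 10531 for 96 h against 72 h, 25336 for late against early, 12844 for middle against both ends. A fit of only the arrays compared gave 10 genes for 4 h against 2 h, 697 for 8 h against 2 h and 1 for 8 h against 4 h, while in each other comparison fitted this way the count stayed within 1.5 times the main one. Within 2 to 8 h the time test called 605 genes and within 24 to 96 h 10365. The median SD between replicates was 0.209, 0.183 and 0.191 at 2, 4 and 8 h and between 0.107 and 0.176 at the later times, and the main fit uses 1 spread per gene for all times. For these lower counts the cause was not tested. With an estimated correlation 1 list passed late against early, and the cause was not tested. With each array (or, for lists and scores, each replicate number) left out in turn, the values ranged from 16659 to 16989 for the time test, from 455 to 1284 for 4 h against 2 h, from 2403 to 4492 for 8 h against 2 h, from 10663 to 11861 for 16 h against 2 h, from 12192 to 13562 for 24 h against 2 h, from 11757 to 13185 for 48 h against 2 h, from 12499 to 13809 for 72 h against 2 h, from 12540 to 13708 for 96 h against 2 h, from 401 to 927 for 8 h against 4 h, from 8683 to 9166 for 16 h against 8 h, from 8128 to 8651 for 24 h against 16 h, from 4057 to 5345 for 48 h against 24 h, from 1792 to 2162 for 72 h against 48 h, from 6081 to 6318 for 96 h against 72 h, from 14574 to 14905 for late against early, from 7481 to 8344 for middle against both ends, from 30 to 31 for gene lists over time, from 36.6 to 45.9 for the F of the mesenchymal minus epithelial score. The direction turned for the late against early changes of ZEB2, CCND1 and MMP9 after quantile normalization (0.22, 0.027, 0.089), for LIFR late against early and IL6ST middle against both ends with the mean of a gene's probes (-0.33, -0.15), and for the median of p53 targets at 4 h against 2 h, near 0 in the values as deposited while its camera test pointed down, under 4 settings (-0.068, -0.043, -0.016, -0.034); the cause was not tested. ZEB2 and LIFR did not pass late against early in the values as deposited. CCND1 and MMP9 passed there, but lost their calls with a common median (adjusted p = 0.437 and 0.917) and without the 16 h arrays (adjusted p = 0.0750 and 0.114). MMP9 also lost its call with an offset of 50 (adjusted p = 0.0564) and without many of the single arrays. Of 5176 values of named genes under alternatives, 4993 kept their side of the threshold, 122 lost the call and 56 gained one. Turns of direction, here and above, were counted only where the main or the alternative value passed. Of 813 list medians, 797 kept direction and side of the threshold. Replicate numbers did not pair the arrays evenly over the design. Same-numbered arrays of different times deviated together with correlations between -0.25 and 0.38 (median 0.09), and 38 of 84 lay above 0.1. Among different-numbered arrays the median was -0.05 and 39 of 168 lay above 0.1. In 5 of 28 pairs of times all 3 same-numbered correlations lay above 0.1. These pairs were 8 h with 48 h and with 96 h, and 24, 48 and 72 h each with 96 h. A shared batch of same-numbered arrays stays open, most clearly there. With a replicate block 5940 genes passed for 48 h against 24 h and 7253 for 96 h against 72 h, more than without it, and 8 lists passed late against early, fewer than without it. With the block, 5 calls of genes fixed in advance were gained and 1 was lost. Gained were STAT3 at 8 h against 2 h (adjusted p = 0.0337), LIF and CDH2 at 48 h against 24 h (0.0338 and 0.0239), CCND1 at 72 h against 48 h (0.0355) and CD83 at 96 h against 72 h (0.0477). The call of ZEB1 at 96 h against 72 h was lost (adjusted p = 0.0503). This ZEB1 call was also lost after quantile normalization (adjusted p = 0.0896), with a common median (0.147), with the mean of its probes (0.336) and with an offset of 50 (0.124). Leaving out any single 72 or 96 h array lost it too. Between 1.09% and 6.58% of probes per array lay at the floor, which limits what dim genes can show.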

Other observations

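The tests of whole-gene regulation, of an array batch, of replicate noise, of other cells and of S phase were chosen only after the result was seen. Of 37 hypoxia and HIF target genes, 11 fell and 4 rose at 8 h against 2 h (camera adjusted p = 0.0499, or adjusted p = 0.214 with an estimated correlation). YAP and TEAD target genes fell in 11 of 26 cases between 48 and 72 h, among them AMOTL2 (-1.74 ± 0.20), GADD45B (-1.61 ± 0.16) and CCN2 (-1.25 ± 0.24), and rose in 1 (camera adjusted p = 2.62e-04, or 0.0297 with an estimated correlation). Housekeeping genes fell in 11 of 25 cases between 72 and 96 h and rose in 2 (adjusted p = 4.99e-04, or 0.0351 with an estimated correlation). Oxidative phosphorylation genes rose in 7 of 41 cases between 48 and 72 h, with none lower (adjusted p = 1.44e-04, or 0.0043 with an estimated correlation).

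From 8 to 16 h and from 16 to 24 h, probes of the same gene disagreed. Intensity-dependent scaling of the arrays is argued against by a correlation of -0.0051 after quantile normalization from 8 to 16 h. In that step the spread of probe changes was 6.48 times their median standard error, more than noise between replicates gives. With 9749 genes called in the step such a ratio was bound to be high, so it is no separate evidence. Regulation of whole genes has no test of its own here, since the correlation of -0.0077 in that step is the pattern itself. A preparation or array batch that splits the times into 2 to 8 h, 16 h and 24 to 96 h is open and untested. These borders were drawn from the same correlations, of which the lowest in the other 5 steps was 0.397. The 16 h arrays also stood apart in their intensities. Between 5.81% and 6.58% of their probes lay under the floor, against at most 4.26% on any other array. Their medians lay between 257 and 272, against at most 252 elsewhere. The labels name no batch, so a batch cannot be told apart from an effect of time here. A change in transcript isoforms with time was not tested.

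Markers of other cell types were lower late than early. Whether a downward drift of dim genes on the arrays explains this stays open: 3 of the 4 marker lists lay within the central 95% of 10000 random lists matched on level, but 1 of these, of alveolar and airway markers, is no test of other cells in a lung adenocarcinoma line. Of the other lists the stromal and endothelial ones lay within, while the blood and immune list, with a median of -0.77, lay below its range of -0.58 to 0.17. Other cells in the early cultures stay open: of 11 measured transcripts abundant in those cells, 2 (COL1A1 and LUM) stood above the median gene at 2 h, but levels of different probes cannot be compared. No biological explanation was tested.

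Replication-dependent histone genes rose from 72 to 96 h. More cells in S phase are argued against by the G1/S and DNA replication list, whose median changed by -1.44. Across 1766 genes probes of the same gene correlated at 0.80 in this step (95% bootstrap interval from 0.766 to 0.823), and 689 of 713 genes called on both moved the same way, so the broad disagreement seen at 16 h is absent here. For the histone genes themselves a probe-specific artifact of that kind stays open, because the 11 histone genes that rose had 1 further probe, which also rose (H2BC5), while a second probe of H4C3, a gene that did not rise, fell (-0.63). Signal shared between near-identical histone copies could not be tested without probe sequences.

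Chance in the grouping of arrays was tested by regrouping. For the time test, for late against early and for middle against both ends, 1 of 100 regroupings of the 24 arrays, the real one, gave as many genes. The highest other counts were 1, 1 and 0. Regrouping mixes arrays of different times, so it shows only that arrays of 1 time resemble each other. It cannot exclude chance differences between cultures or runs, since the 3 arrays of a time may be technical repeats. For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real count and the highest of the other 9 splits were 1002 against 253 for 4 h against 2 h, 4164 against 997 for 8 h against 2 h, 11971 against 0 for 16 h against 2 h, 13528 against 1 for 24 h against 2 h, 13157 against 0 for 48 h against 2 h, 13773 against 1 for 72 h against 2 h, 13670 against 1 for 96 h against 2 h, 717 against 482 for 8 h against 4 h, 9749 against 1 for 16 h against 8 h, 9309 against 0 for 24 h against 16 h, 5474 against 2 for 48 h against 24 h, 2723 against 1 for 72 h against 48 h, 6901 against 1 for 96 h against 72 h.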
